A study of Homo sapiens with 6 samples.

How the data were processed

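Anti-ISG20L2 chromatin immunoprecipitation (ChIP) was followed by sequencing in A549 cells, a human lung adenocarcinoma line, 8 h after infection with herpes simplex virus 1 (HSV-1) at a multiplicity of infection (MOI) of 1. ISG20L2 is a nucleolar exonuclease of the ISG20 family. Of the 6 samples, 3 were ChIP replicates and 3 were inputs without antibody. Each ChIP replicate came with 1 peak list. No processed file of the inputs was used here, and no uninfected sample was analysed here, so the comparisons were those between the 3 ChIP lists and between each list and random genomic placement. The labels do not say whether the replicates came from separate cultures, so differences between them may be technical. The p-values measure departure from random placement, random counts or shuffled peaks, regions and chromosomes. They do not measure variation between replicates. Peak names inside the lists carried the number 2 in the lists of replicates 1 and 3 and the number 3 in the list of replicate 2. Each list was assigned to its sample by the series record and not by these names.

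Chromatin was cross-linked and digested with a commercial enzymatic kit, per the labels' protocols. Reads were aligned to GRCh38.p14 with BWA mem 0.7.12 and peaks were called with MACS2 2.1.0, per the submitters' processing notes. The control used in peak calling, the p-value threshold and the fragment length are not given in the sources used here. The fold enrichment deposited by the authors for each peak is a ratio of the ChIP pileup at the summit to the local background, and it was used to describe, rank or filter peaks and, over shared regions, to correlate replicates. The authors also deposited the −log10 of an unadjusted p-value and the −log10 of a q-value for each summit. The integer score that the authors deposited equalled 10 times the −log10 p, rounded down, in 100% of summits of each list and was not used. The largest p in the lists of replicates 1, 2 and 3 was 0.00461, 0.00493 and 0.00496, so the lists had been thresholded on unadjusted p.

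Identical intervals with several summits were kept once, with the strongest summit. All sequence names in the lists were found in the reference (0 unmatched), and 0 peaks ran past the end of a sequence. Genes came from GENCODE 44 (62681 genes), which covers chromosomes 1 to 22, X, Y and the mitochondrial genome. Other sequences therefore had no feature. Transfer RNA genes came from RefSeq, and 406 of 443 rows passed a T-loop motif check. Coordinates are GRCh38, counted from 1.

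The number of ChIP fragments and the background under each summit were recovered from the deposited fold enrichment and p, since MACS2 computes both from them. A solution within 0.2% of the −log10 p was found for 100% of summits in each list. The median was 8 fragments per summit in replicate 1, 10 in replicate 2 and 8 in replicate 3. The middle 95% of summits spanned 6 to 20, 7 to 28.6 and 5 to 16 fragments. The background equalled its lowest value, 1.01, 1.03 and 1.08 fragments, at 79.5%, 71.3% and 75.6% of summits. Fragment numbers under a summit are unscaled ChIP fragments, while the background is on the scale of the control. The ChIP pileup was scaled to it by 0.698, 0.612 and 0.819, so the 2 cannot be divided directly. With so few fragments under a summit, a change of 1 fragment visibly moves its fold enrichment. ChIP libraries were 1.43, 1.63 and 1.22 times as deep as their controls. Total read numbers are not given in the sources used here. Intervals and p-values of counts cover counting error only.

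Lists were compared by overlap of at least 1 bp against 1000 random placements of the peaks of 1 list on the same chromosome outside runs of N, with the widths kept. The smallest one-sided p of that test was 0.001. Union regions were the merged peaks of the 3 lists, and shared regions were those with a peak of at least 2 replicates. Promoters (within 1 kb of a transcription start site), exons, introns and intergenic sequence were assigned by region midpoint in that priority. Sequence near a gap lay within 100 kb of a run of N of at least 10 kb. GC content, short tandem repeats (period 1 to 6 bp, runs of at least 20 bp) and 6-mers were compared with placements as well, with 100 placements for the 6-mers of the single lists. The smallest two-sided p was 0.002 with 1000 placements and 0.0198 with 100. The reference was in upper case, so a planned share of soft-masked bases was not computed. Benjamini-Hochberg adjustment was applied within each family. Medians and correlations of fold enrichment were tested with 100000 permutations. Chromosome densities were shares of peaks divided by shares of sequence without N, with exact Poisson 95% intervals, and the 5 acrocentric chromosomes (13, 14, 15, 21 and 22) were set against the other autosomes.

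The 19 gene lists covered ribosomal RNA genes, ribosomal RNA pseudogenes, snoRNA, snRNA and tRNA genes, histone genes, ribosomal protein genes, olfactory receptor genes, ZNF zinc finger genes, ribosome biogenesis genes, interferon-stimulated genes, DNA-sensing genes, cell death genes, nucleases and DNA repair genes, genes at common fragile sites, highly transcribed control genes, lung epithelial genes, immune cell markers, and fibroblast and endothelial markers. The pattern for ribosomal RNA genes also took 5S pseudogenes. That for snRNA genes also took snRNA pseudogenes, such as RNU6-1048P, and most snRNA members with a peak were of this kind. A gene counted when a region lay in its body or within 5 kb. Named regions were fixed by a rule: the 25 regions with the highest mean fold enrichment, taken first from those in all 3 replicates, the 3 strongest peaks of each replicate, and up to 4 members per list. ISG20L2 and the 5S and 45S ribosomal RNA genes were always looked up. Further 45S units were found by aligning RNA45SN1 with minimap2 2.31 (alignments of at least 10 kb).

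Sequence was called multi-copy when the median number of copies of its 31-mers in the assembly was at least 2. Tandem periods up to 400 bp were found by comparing a window of 1500 bp with itself at each shift, and a period was called at an identity of at least 0.4. These repeat measures, and the 20000 placements they were compared with, were chosen after the lists had been examined. Those placements drew on the peaks of the 3 lists in equal parts, each kept on its own sequence. They were not matched to the sequences that held the shared regions. All designs, gene lists, the naming rule and most alternatives were fixed before the data were examined. Alternatives included −log10 q of at least 5, fold enrichment of at least 5, equal list lengths of 775, leaving out each replicate, regions in all 3 replicates, primary chromosomes only, reciprocal overlap of 50%, summits within 200 bp, GC-matched placement, promoters within 5 kb, protein-coding genes only, gaps within 1 Mb and genes without a margin or within 50 kb. The alternative with protein-coding genes only applied to promoters and gene bodies, and exons of all genes were kept. Alternatives added later were placement within 1 Mb, q of at most 0.05 and single-copy peaks only.

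The overlap test was tested on simulated data with 30 planted overlaps among 775 peaks. It found them in 20 of 20 simulations and passed p of 0.05 in 1 of 20 simulations without them. With 30 promoter regions planted among 137, the promoter test passed in 20 of 20 simulations, against 2 of 20 without, and 10 planted interferon-list genes were found in 20 of 20. The planted promoter and gene-list effects were larger than those observed here, so they do not give the power at the observed sizes. Fragment numbers were recovered at 100% of 1579 simulated summits. These were simulated with the formula that the recovery inverts, so this checks the computation only. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9 were used.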

Results

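DNA bound by ISG20L2, a nucleolar exonuclease, was profiled by ChIP-seq in HSV-1-infected A549 cells, a human lung adenocarcinoma line, at 8 h and an MOI of 1. The series title places the study around nucleolar ISG20L2 and the degradation of genomic DNA in dying cells, so the question addressed was where on the host genome the antibody enriched DNA. The 3 ChIP replicates had 1949, 775 and 12345 peak intervals, covering 703, 290 and 4392 kb. Median peak width was 320, 340 and 313 bp. Fold enrichment, as the authors' peak caller gave it, had a median of 3.28, 3.21 and 3.24 and a maximum of 6.77, 6.53 and 13.96. Only 50 of 1952 summits in replicate 1 (2.56%), 20 of 777 in replicate 2 (2.57%) and 1666 of 12387 in replicate 3 (13.4%) had a q of at most 0.05. A q of 1 was recorded for 94.9%, 93.1% and 27.9% of summits. The median number of ChIP fragments under a summit was 8, 10 and 8.

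The strongest region found in all 3 replicates lay in an intron of NBPF1, a member of the repeated neuroblastoma breakpoint family, at chromosome 1, 16565247 to 16565733. Its fold enrichment was 5.21 ± 1.35 (SD, n = 3). Introns of NBPF12 (chromosome 1, 146985379 to 146986307) and NBPF11 (chromosome 1, 148107303 to 148107811) also held regions in all 3 lists, at 4.24 ± 1.54 and 3.77 ± 0.365. A q of at most 0.05 was reached at NBPF1 in replicates 1 and 3, and at NBPF12 and NBPF11 in replicate 3 alone. Presence in a list did not require that q, and with it 9 regions in place of 23 were in all 3 lists. The scaffold GL000225.1, a sequence assigned to chromosome 14 without a position, held 7 of the 23 regions found in all 3 lists. Its strongest, at 133496 to 133998, reached 4.78 ± 0.549. The scaffold GL000216.2 held a pair, led by 149364 to 149843 at 4.50 ± 1.18. A pericentromeric region of chromosome 3 (91177700 to 91178032) reached 4.66 ± 0.563, and KI270330.1 (947 to 1511) reached 4.0 ± 0.686.

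Other regions present in all 3 lists lay beside DUX4L17 on Y (11312336 to 11312801, 3.92 ± 0.530) and in an intron of DUX4 on chromosome 4 (190179389 to 190179924, 2.68 ± 0.633). DUX4 encodes a homeobox factor inside the D4Z4 macrosatellite array. The pseudogene ROCK1P1 at the end of chromosome 18 carried a pair, at 110184 to 110777 (intron, 3.23 ± 0.705) and 107917 to 108605 (promoter, 2.49 ± 0.345). Regions not called multi-copy included introns of ARHGEF18 (chromosome 19, 7450389 to 7451045, 3.64 ± 0.923), and CACNA1C, an L-type calcium channel gene (chromosome 12, 2255728 to 2256213, 3.53 ± 0.509). The ARHGEF18 region still passed the tandem repeat call, with an identity of 0.602 at a period of 34 bp. The CACNA1C region fell just short of 0.4, with 0.382 at 30 bp. At ARHGEF18 and CACNA1C only replicate 3 had a q of at most 0.05. In replicates 1, 2 and 3 the background was 4.0, 3.0 and 2.83 fragments at ARHGEF18 and 4.0, 2.0 and 6.0 at CACNA1C. The lowest values were 1.01, 1.03 and 1.08, so these 2 regions cannot be taken as unique sequence. The lncRNA gene ENSG00000280136 (chromosome 17, 117074 to 117579) was at 3.53 ± 0.799, and the promoter of the pseudogene ENSG00000282501 (X, 9405610 to 9406611) at 3.47 ± 0.0320. ENSG00000280136 reached a q of at most 0.05 in none of the lists and ENSG00000282501 in replicate 3 alone. The lowest of the named regions, on chromosome 17 (26603685 to 26604315), was at 1.81 ± 0.126. The naming rule was filled with regions of 2 lists: GL000214.1, 120787 to 121234, at 9.13 ± 6.83 (n = 2), and chromosome 10, 40980982 to 40981302, at 6.32 ± 0.468 (n = 2). The remaining GL000225.1 and GL000216.2 regions ranged from 3.23 to 4.70.

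Within the single lists, the NBPF1 intron was strongest in replicate 1 (6.77), followed by GL000225.1, 131518 to 131999 (6.74), and the chromosome 10 region at 40980982 (6.66). In replicate 2 the ZFP37 promoter led (chromosome 9, 113056139 to 113056784, 6.53), ahead of the same chromosome 10 region (5.99) and chromosome 4, 50492143 to 50492483 (5.93). ZFP37 encodes a zinc finger protein. In replicate 3 the strongest peaks were GL000214.1 at 120787 (13.96), chromosome 10, 40971773 to 40972107 (11.2), and chromosome 21, 10273947 to 10274303 (8.37). The chromosome 4, the second chromosome 10 and the chromosome 21 peaks were each in 1 list.

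Few regions recurred between replicates, but more than random placement gave. Replicates 1 and 2 shared 41 peaks of the shorter list of 775 (random mean 2.25, 18.2-fold), replicates 1 and 3 shared 111 of 1949 (10.9, 10.2-fold), and replicates 2 and 3 shared 60 of 775 (4.51, 13.3-fold). Each p was 0.001, also after adjustment over the 3 pairs, the smallest that 1000 placements can give. Of 14880 union regions, 14715 (98.9%) came from 1 list, 142 from 2 lists and 23 from all 3. The 165 shared regions exceeded the random mean of 16.6 by 9.95-fold, and the 23 regions of all 3 lists exceeded 0.53 by 43.4-fold (each p 0.001). At a fold enrichment of at least 5, replicates 2 and 3 shared 0 peaks. With placements matched on GC, the random mean of shared regions was 26.7 and the excess 6.18-fold. In single-copy peaks the excess remained, at 79 shared regions against 9.27 (8.52-fold) and 4 regions of all 3 lists against 0.01.

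**Figure D1:**
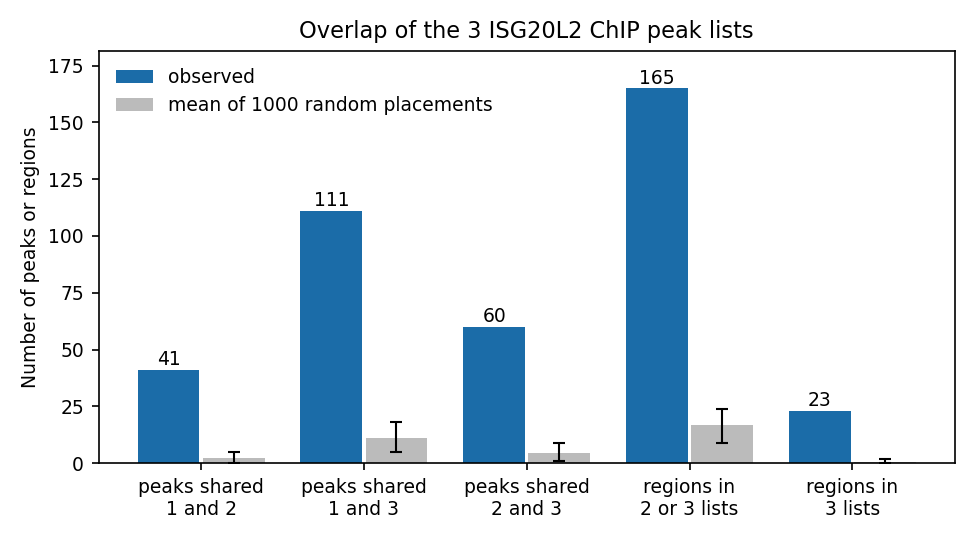
Number of peaks shared by each pair of replicates and of union regions found in 2 or 3 lists (blue), beside the mean of 1000 random placements (grey, bars over the middle 95% of placements). The observed counts of 41, 111, 60, 165 and 23 stand above the random means of 2.25, 10.9, 4.51, 16.6 and 0.53.

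Peaks in shared regions had slightly higher fold enrichment than the other peaks of their list in replicates 2 and 3. The medians were 3.5 against 3.21 in replicate 2 (78 and 697 peaks, difference 0.289, adjusted permutation p 0.0159) and 3.61 against 3.24 in replicate 3 (147 and 12198 peaks, difference 0.366, adjusted permutation p 0.0264). In replicate 1 the medians were 3.36 and 3.25 (129 and 1820 peaks), and the difference of 0.110 did not pass the two-sided test (adjusted permutation p 0.211) and ranged from 0.0151 to 0.230 with another replicate left out. Among peaks with q of at most 0.05 the shared peaks had the lower median in all 3 lists, with differences of −0.732, −2.51 and −0.403. With equal list lengths the difference in replicate 3 was −0.791, and with single-copy peaks it was 0. Without replicate 1 it did not pass (0.395, permutation p 0.0570).

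Across the shared regions of a pair, fold enrichment was correlated between replicates 2 and 3 (60 regions, Pearson's r 0.414, permutation p 0.0011, adjusted 0.0033; Spearman's rho 0.479, permutation p 0.00019, adjusted 0.00057). It was also correlated between replicates 1 and 3 (111 regions, r 0.286, permutation p 0.00476, adjusted 0.00714; rho 0.325, permutation p 0.00055, adjusted 0.000825). Between replicates 1 and 2 the 41 regions gave r 0.314 (permutation p 0.0451, adjusted 0.0451) and rho 0.234 (permutation p 0.142, adjusted 0.142). Without the 2 regions farthest from the median of the first-named replicate, r was 0.352 for replicates 1 and 2, 0.301 for 1 and 3 and 0.442 for 2 and 3. Regions extreme only in the second-named replicate stayed in, such as GL000214.1 at 13.96 in replicate 3. Regions are not independent replicates, and in single-copy peaks rho between replicates 1 and 3 was −0.0185.

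Shared regions lay in repeated sequence more often than regions of 1 list, although replicates also overlapped in single-copy peaks. Multi-copy sequence made up 80 of 165 shared regions (48.5%, exact 95% interval 40.6 to 56.4), 2030 of 14715 regions of 1 list (13.8%, 13.2 to 14.4) and 15.8% of random placements. The odds ratio of shared against single-list regions was 5.88 (Fisher's exact test, adjusted p 2.06e-25 over 20 tests). Among the 23 regions of all 3 lists the share was 69.6% (47.1 to 86.8), against 45.1% (36.7 to 53.6) of the 142 in 2 lists (adjusted p 0.0464). On primary chromosomes alone the shares were 42.2% of the shared and 13.2% of the single-list regions (odds ratio 4.80, adjusted p 3.22e-16). These repeat measures were chosen after the regions had been seen. Some shared regions lie in the same repeat array and are not independent, so these p-values are too small.

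Tandem repeats with a unit of 67 to 70 bp, or its double, covered 25 of 165 shared regions (15.2%, 10.1 to 21.5) and 13 of the 23 in all 3 lists (56.5%, 34.5 to 76.8). The share of shared regions was 34.1% without replicate 3 and 6.67% on primary chromosomes. They covered 0.29% of random placements (Fisher's exact test, odds ratio 61.4, adjusted p 4.85e-32) and 0.156% of single-list regions, which were below placements (odds ratio of shared against single-list regions 114, adjusted p 5.00e-36). Beta satellite DNA has a unit of this length. The 25 shared regions lay on GL000225.1 (13), chromosome 18 (4, 107156 to 110777, around ROCK1P1), GL000216.2 (3), chromosome 4 (2, 190177668 to 190179924, at DUX4), Y (2) and chromosome 10 (1, 133688250 to 133688594). Tandem repeats with the unit length of centromeric alpha satellite, within 2 bp, or its double, covered 16 of 165 shared regions (9.70%, 5.64 to 15.3) against 2.39% of random placements (odds ratio 4.39, adjusted p 3.94e-06). Single-list regions were below placements, at 0.666%, which gave an odds ratio of 16.0 against them (adjusted p 2.11e-13). The alpha-length regions lay on chromosomes 3 (4), 11 (4), 10 (3), 7, 9 and 17 (1 each) and KI270538.1 (2). Regions of the same repeat array are not independent, while Fisher's exact test and the intervals count each as a separate trial. These p-values are therefore too small and the intervals too narrow. At q of at most 0.05, 80.0% of replicate 1, 80.0% of replicate 2 and 24.3% of replicate 3 peaks were multi-copy.

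**Figure D2:**
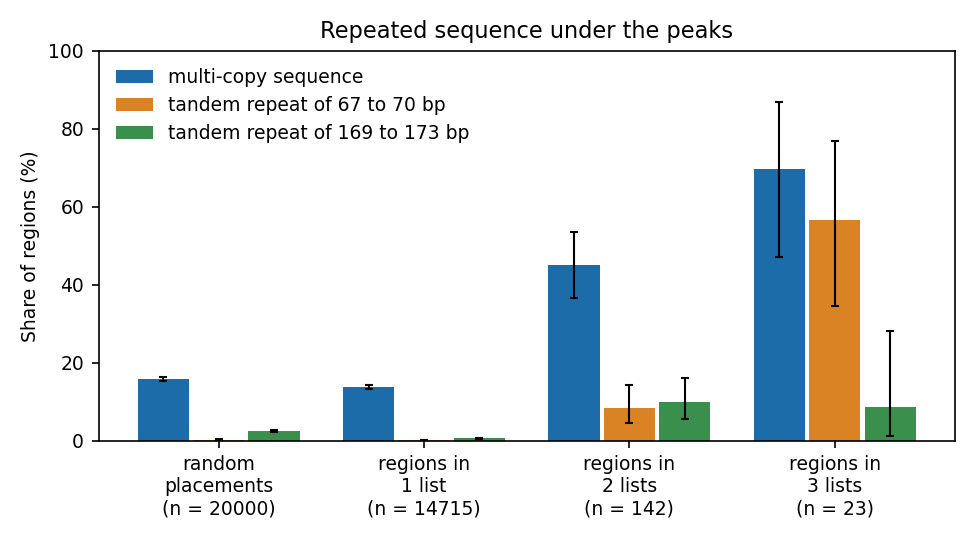
Share of regions in multi-copy sequence (blue) and in tandem repeats of 67 to 70 bp (orange) or of the alpha satellite unit length (green), doubles included, for 20000 random placements and for regions found in 1, 2 and 3 lists, with exact 95% intervals. The multi-copy share is 15.8%, 13.8%, 45.1% and 69.6% from left to right.

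A minority of the shared regions, 13.3% of 165, lay within 100 kb of an assembly gap, against 1.81% of placements (p 0.002). With single-copy peaks only, 0 of 79 shared regions did (random mean 1.0%). The per-list shares were 1.95%, 3.23% and 1.61% against 1.13%, 1.34% and 1.09% (p 0.004, 0.002 and 0.002), and in single-copy peaks they turned to 0.305%, 0.161% and 0.529% against 1.01%, 1.08% and 1.06%. GC content averaged 48.1% in shared regions against 41.8% in placements, and 47.4%, 48.5% and 52.8% in the lists of replicates 1, 2 and 3 against 41.1%, 41.1% and 41.0% (each p 0.002, the smallest possible). Short tandem repeats took 0.172% of bases in shared regions against 0.421% (p 0.054). In replicates 1, 2 and 3 they took 0.131%, 0.329% and 0.108% against 0.357%, 0.366% and 0.353% (p 0.002, 0.59 and 0.002). Of 2080 6-mers, 343 were more and 276 less frequent in shared regions than in placements at adjusted p of 0.05. The higher 6-mers had a median of 4 G or C bases and the lower ones 1. In the single lists 1283, 1134 and 1935 6-mers passed.

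Promoters held 16.2% of the 136 shared regions on annotated sequence against 8.15% of placements (adjusted p 0.032). The single lists gave 9.06%, 11.1% and 8.77% against 7.42%, 7.79% and 7.25% (adjusted p 0.080, 0.024 and 0.002). Shared promoter regions named above were those of ENSG00000282501, ROCK1P1 and ZFP37. Exons held 0 of the 136 shared regions against 3.24% (adjusted p 0.048), introns 44.1% against 51.1% (adjusted p 0.16) and intergenic sequence 39.7% against 37.5% (adjusted p 0.67). In replicate 3 exons held 4.31% against 3.31%, introns 48.1% against 52.2% and intergenic sequence 38.8% against 37.2% (each adjusted p 0.002). With placements matched on GC, the promoter call of the shared regions ended (9.77% of placements, adjusted p 0.0639), that of replicate 2 ended (9.72%, adjusted p 0.759), and in replicate 3 the promoter share of 8.77% lay below the 11.8% of placements (adjusted p 0.00266). The exon calls ended as well, at 3.80% of placements for shared regions (adjusted p 0.0639) and 4.56% for replicate 3 (adjusted p 0.21). With promoters taken within 5 kb the shares of replicates 1 and 3, 23.3% each, lay below placements (26.1% and 26%), and without replicate 1 or 2 the shared-region call ended (12.2% and 12%, adjusted p 0.354 and 0.380) while without replicate 3 it held (33.3%, adjusted p 0.008). Leaving out any replicate ended the exon call of shared regions (adjusted p 0.354 to 0.685).

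No gene list stood apart in the shared regions: 0 of 19 passed, and 0 had an unadjusted p under 0.05 in the randomisation test. Lists with a member were interferon-stimulated genes (1 of 50, random mean 0.091), with RSAD2, an antiviral radical SAM enzyme, and olfactory receptors (1 of 400, 0.435), with OR2A7. ZNF genes (1 of 476, 1.44) gave ZNF181, common fragile site genes (1 of 25, 1.52) gave PDE4D, and immune cell markers (1 of 26, 0.046) gave FCGR3A, each with adjusted p 1. The RSAD2 region (chromosome 2, 6888526 to 6889184, intron) had a fold enrichment of 3.09 ± 0.217 (n = 2, replicates 1 and 3). The OR2A7, ZNF181, PDE4D and FCGR3A regions were at 3.22 ± 1.08, 3.86 ± 0.0648, 3.39 ± 0.843 and 2.96 ± 0.526 (n = 2). The FCGR3A region was multi-copy. Shared regions were found at 0 of 536 ribosomal RNA genes (pseudogenes included), 0 of 515 ribosomal RNA pseudogenes, 0 of 553 snoRNA, 0 of 1831 snRNA (pseudogenes included), 0 of 406 tRNA, 0 of 73 histone and 0 of 80 ribosomal protein genes. They were also found at 0 of 65 ribosome biogenesis, 0 of 26 DNA-sensing, 0 of 46 cell death, 0 of 42 nuclease and DNA repair, 0 of 33 highly transcribed, 0 of 33 lung epithelial and 0 of 17 fibroblast and endothelial genes. Random placement put at most 0.907 members in any of these.

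In the list of replicate 3, all gene lists but ribosomal RNA genes, ribosomal RNA pseudogenes and olfactory receptors lay below their random mean, and 3 of the 19 passed adjustment. They were snRNA genes with their pseudogenes (50 of 1831 against 78.8), ZNF genes (49 of 476 against 72.7), and nuclease and DNA repair genes (3 of 42 against 9.29), each with adjusted p 0.038. Most of the snRNA members with a peak were pseudogenes, so functional snRNA genes were hardly tested. The repair genes were ATR, a DNA damage kinase (3.96), WRN, a RecQ helicase (3.24), and XRCC4, an end-joining factor (2.85). Placement within 1 Mb ended all 3 calls (random means 73.9, 55.5 and 7.15, adjusted p 0.152, 0.698 and 0.405), as did equal list lengths, q of at most 0.05 and both stricter thresholds, and GC-matched placement gave 10 lists in place of 3. The repair call also ended on primary chromosomes, with gene bodies only and in single-copy peaks (adjusted p 0.0633, 0.121 and 0.0868), and the snRNA call with gene bodies only (0 members, adjusted p 0.203). Olfactory receptor genes held more, 41 of 400 against 26.9, without passing adjustment (adjusted p 0.076). The interferon-stimulated list had 6 of 50 members against 7.71 in replicate 3, among them IFIT2 and OAS2 (3.64 each), the ribosome biogenesis list 5 of 65 against 11.2 (adjusted p 0.099) and the cell death list 5 of 46 against 8.05. In replicates 1 and 2, 0 of 19 lists passed. The lowest p there was that of common fragile site genes in replicate 1 (7 of 25 against 12.5, p 0.014, adjusted 0.27).

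Peaks were spread unevenly over the chromosomes, and alike in the 3 lists. Relative to sequence length, chromosome 20 held 2.25 ± 0.353 and chromosome 2 held 2.07 ± 0.235 times the average peak density (SD, n = 3), followed by chromosomes 9 (1.44 ± 0.247), 10 (1.39 ± 0.117) and 5 (1.38 ± 0.109). Chromosomes 21 (0.173 ± 0.119), 13 (0.240 ± 0.101), 22 (0.264 ± 0.136), 4 (0.302 ± 0.0917), X (0.321 ± 0.107), 6 (0.350 ± 0.185) and 18 (0.360 ± 0.165) were low, as was Y (0.139 ± 0.0920). Unplaced and other scaffolds held 5.69 ± 2.25 times the average. The mitochondrial genome had 4, 4 and 0 peaks, 1 of them shared, at MT-CYB (14665 to 15382, 4.34 ± 0.318, n = 2).

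Across chromosomes 1 to 22 and X, density correlated between replicates 1 and 2 (r 0.952, rho 0.900), 1 and 3 (r 0.967, rho 0.940) and 2 and 3 (r 0.930, rho 0.934). Each permutation p was 1e-05, the smallest possible, and 2.67e-05 after adjustment over 8 relations. Without the 2 chromosomes farthest from the median of the first-named replicate, r was 0.918, 0.947 and 0.893. At q of at most 0.05 the mean densities of chromosomes 2 and 20 fell to 0.934 and 0.631. Replicate 3, with 1656 such peaks, kept 2.07 and 1.89 there, while replicates 1 and 2 had 3 and 0 such peaks on chromosome 2 and 0 on chromosome 20.

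**Figure D3:**
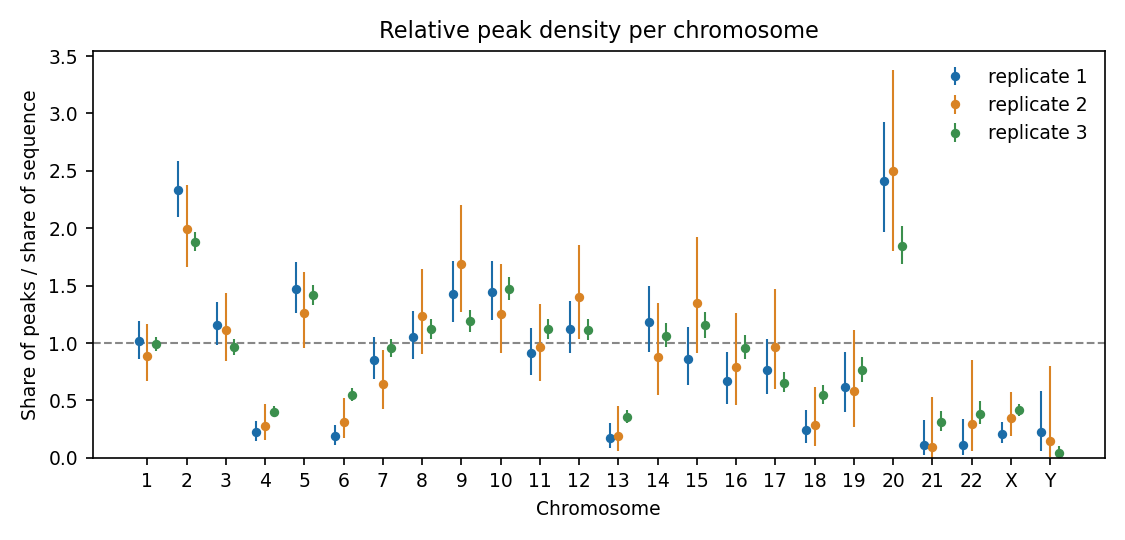
Share of peaks divided by share of sequence without N on each chromosome in replicates 1 (blue), 2 (orange) and 3 (green), with exact Poisson 95% intervals and a dashed line at 1. Chromosomes 2 and 20 stand at a mean of 2.07 and 2.25, and chromosomes 13, 21 and 22 at 0.240, 0.173 and 0.264.

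The acrocentric chromosomes, whose short arms carry the ribosomal DNA arrays, had a lower peak density than the other autosomes over sequence without N. The assembly holds only collapsed copies of those arrays, so this density does not measure them. The ratio was 0.535, 0.605 and 0.675 in replicates 1, 2 and 3 and 0.160 for shared regions. Random draws by sequence length gave about 1.00 (each p 0.002 by that test). In the lists the low value came from chromosomes 13, 21 and 22, while chromosomes 14 and 15 stood at 1.0 ± 0.153 and 1.12 ± 0.247. Shared regions numbered 2 on chromosome 13 and 1 on chromosome 14, with none on 15, 21 or 22. Low list density was not particular to acrocentric chromosomes, since chromosomes 4, 6 and 18 stood at 0.302, 0.350 and 0.360. At q of at most 0.05 the ratios of replicates 1, 2 and 3 were 0.244, 0 and 0.671 (p 0.21, 0.298 and 0.002), and at −log10 q of at least 5 they were 0, 0 and 0.922 (p 1 each). At equal list lengths the ratio of replicate 3 did not pass (0.792, p 0.066), nor did the shared-region ratio without replicate 3 (0.262, p 0.27). The shared-region ratio kept its call in 4 of 10 alternatives. At a fold enrichment of at least 5 the ratios of replicates 1, 2 and 3 were 0.487, 1.24 and 0.806, without passing.

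The ISG20L2 gene itself (chromosome 1, 156721891 to 156728766) had 0 peaks within 5 kb in all 3 lists, as did the 17 5S ribosomal RNA genes RNA5S1 to RNA5S17 (chromosome 1, 228610268 to 228646158). The 45S ribosomal RNA units in the assembly lie on chromosome 21, KI270733.1 and GL000220.1 and add up to 91.4 kb over 7 units. They held 0, 0 and 2 peaks in replicates 1, 2 and 3, against 0.0604, 0.0240 and 0.383 at the genome-wide density (exact binomial test in replicate 3, p 0.057, adjusted 0.171). The pair lay on KI270733.1 at 135596 to 136200 (fold enrichment 2.0) and 168825 to 169139 (2.57), and the first of these lay mostly in the spacer, since the unit ends at 135632. The units are near-identical and collapsed copies of larger arrays, so a peak cannot be assigned to 1 unit.

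**Figure D4:**
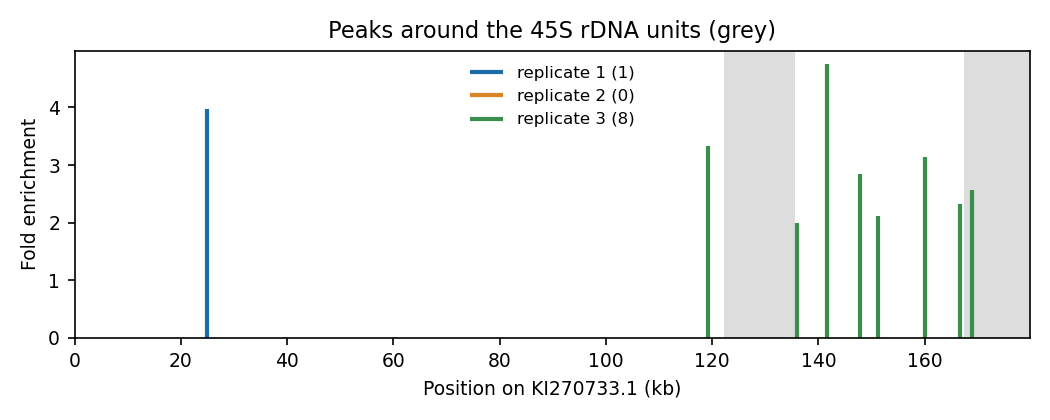
Fold enrichment of each peak on the scaffold KI270733.1 (x axis in kb), with the 2 copies of the 45S unit in grey, for replicates 1 (blue, 1 peak), 2 (orange, 0 peaks) and 3 (green, 8 peaks). The tallest peak, 4.75 at 141534 to 141830 in replicate 3, lies between the units.

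Replicate 3 differed from the other lists in the sequence of its peaks. It held 6.33 times as many intervals as replicate 1 and 15.9 times as many as replicate 2. Below 45% GC the lists of replicates 3 and 1 held 644 and 623 peaks, a ratio of 1.03. The ratio was 3.53 at 45 to 50% GC, 11.4 at 50 to 55% and 27 at 55% or more (4110 against 152 peaks). Against replicate 2 the ratios were 3.05, 9.42, 26.2 and 41.9.

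**Figure D5:**
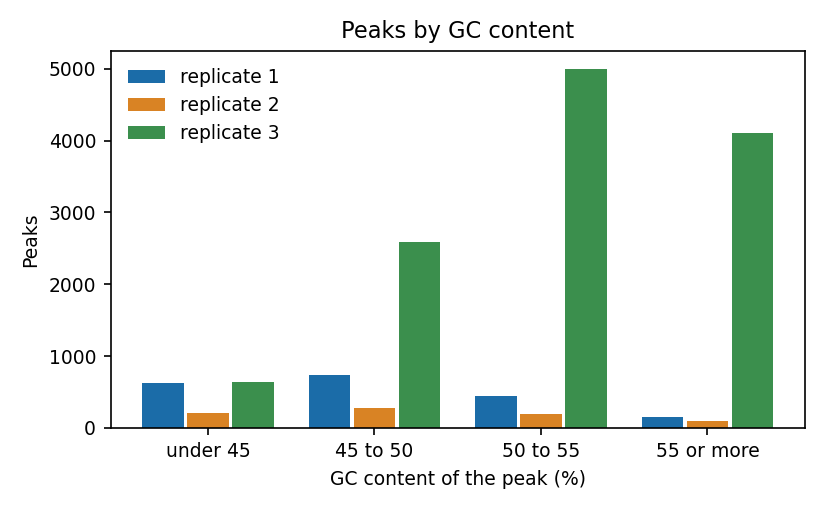
Number of peaks by GC content of the peak (percent) in replicates 1 (blue), 2 (orange) and 3 (green). Replicates 3 and 1 hold 644 and 623 peaks below 45% GC, and 4110 and 152 at 55% or more.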

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

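The alternatives with q of at most 0.05, single-copy peaks only and placement within 1 Mb were chosen after the data had been examined. Over the comparisons, 161 alternative values kept their side of the threshold, 39 fell short of it, 7 newly passed it and 9 reversed. Among the values per list, gene list, region and chromosome, 1198 kept theirs, 41 fell short, 27 newly passed, 82 moved and 31 reversed. For tests, a reversal was counted only where the main or the alternative value passed. A value said below to have turned changed its side of placements, or of 1 for densities. It did not necessarily pass there. Values that passed in neither setting were counted as kept even where their direction changed. The overlap of replicates 1 and 2 and of replicates 1 and 3 kept its call in 11 of 11 alternatives each, that of replicates 2 and 3 in 10 of 11, and the regions of at least 2 replicates in 13 of 13. The promoter share kept it in 4 of 14 and the exon share in 2 of 14. Stricter thresholds left few regions to test: shared regions fell from 165 to 11 at −log10 q of at least 5 and to 3 at a fold enrichment of at least 5. No paired analysis was possible because the inputs that share replicate numbers with the ChIP samples had no files here.

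At −log10 q of at least 5, shared regions gave 20% promoters, 0% exons, 9.09% near a gap, GC of 47.0% and an acrocentric ratio of 0, none past the threshold. There the fold difference in replicate 3 reversed to −0.939, and rho between replicates 1 and 3 was 0.430 without passing. The relative densities of chromosomes 2, 9 and 20 turned to 0.0610, 0.120 and 0.229, and those of 18 and Y to 6.46 and 8.55. Few peaks lay behind these means, since replicates 1 and 2 had only 50 and 20 peaks even at q of at most 0.05. At a fold enrichment of at least 5, replicates 2 and 3 shared 0 peaks and 0 regions were in all 3 lists. Promoters and sequence near a gap turned to 0%, exons were at 0%, GC at 41.7% and the acrocentric ratio at 0. In replicate 3 intergenic sequence turned to 37.0% (37.3% of placements), and the snRNA and ZNF lists to 3 members each (random means 1.79 and 2.57), none past the threshold. The acrocentric ratio of replicate 2 turned to 1.24, and the densities of chromosomes 20, 22 and Y to 0.593, 1.49 and 3.51.

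With equal list lengths, exons were at 0% and the acrocentric ratio at 0.350 without passing, introns passed at 30.4%, the fold difference of replicate 1 passed at 0.109, that of replicate 3 reversed to −0.791, and intergenic sequence in replicate 3 turned to 36.2%. On primary chromosomes, short tandem repeats passed at 0.0460%, rho between replicates 1 and 2 passed at 0.405, and the fold difference of replicate 3 fell short at 0.20. With reciprocal overlap the difference of replicate 1 passed at 0.359. For regions in all 3 lists, promoters (15.4%), exons (0%), GC (46.0%) and the acrocentric ratio (0) fell short.

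With GC-matched placement, promoters (16.2%) and exons (0%) of shared regions fell short, and those of replicate 3 (8.77% and 4.31%) lay below placements. With promoters within 5 kb, shared promoters (32.4%) and exons (0%) fell short, and the promoter shares of replicates 1, 2 and 3 turned (23.3%, 26.5% and 23.3%). That of replicate 2 was level with its placements (26.6%) and did not pass. With promoters and gene bodies of protein-coding genes only, promoters (8.09%) and exons of all genes (2.21%) fell short, introns (25.7%) and intergenic sequence (64%) passed, and promoters of replicate 3 turned (4.16%). Within 50 kb of genes, the ribosomal RNA and ribosomal RNA pseudogene lists of replicate 3 turned to 142 and 134 members, below placements. Within 1 Mb of a gap, replicate 3 turned to 7.32% against 7.67% of placements, without passing.

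At q of at most 0.05, promoters (17.6%), exons (0%), the acrocentric ratio (0) and rho between replicates 1 and 3 (0.363) fell short. The fold differences reversed to −0.732, −2.51 and −0.403, intergenic sequence in replicate 3 turned to 36.4%, and the densities of chromosomes 2, 9, 20, 18 and Y turned to 0.934, 0.847, 0.631, 2.34 and 4.18. In single-copy peaks, promoters (16%), exons (0%) and the fold differences of replicates 2 and 3 (0.184 and 0) fell short. Shares near a gap turned to 0% for shared regions and to 0.305%, 0.161% and 0.529% for the lists, and rho between replicates 1 and 3 turned to −0.0185. In each of these the cause was not tested.

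Leaving out a replicate, promoters ranged from 12% to 33.3%, and the call ended in 2 of 3 settings. Exons ranged from 0% to 0%, and the call ended in 3 of 3 (adjusted p 0.354 to 0.685). The acrocentric ratio ranged from 0.0863 to 0.262 and its call ended in 1 of 3, and the fold difference of replicate 3 ranged from 0.394 to 0.395 and its call ended without replicate 1 (permutation p 0.0570). The multi-copy share of shared regions, 48.5% with all lists, was 52.7% to 53.7% without a replicate, 69.7% of 66 regions at equal list lengths, 81.8% of 11 at −log10 q of at least 5, 87.1% of 31 at q of at most 0.05 and 100% of 3 at a fold enrichment of at least 5.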

Other observations

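The tests of the ribosomal spacer, of multi-copy sequence within each list, of single-copy peaks per chromosome and of the size of the replicate 3 list were chosen after the result was seen. Downstream of the 45S ribosomal RNA units, in the intergenic spacer that separates repeats in the ribosomal DNA arrays, replicate 3 held 10 peaks within 30 kb (150 kb over the units in all). The genome-wide density would give 0.628 (15.9-fold, exact binomial p 1.48e-09, adjusted 8.90e-09 over 6 tests), and 7 of them had a q of at most 0.05. That baseline assumes even placement, while the peaks of replicate 3 were concentrated in sequence of high GC. Backgrounds under the 10 peaks ran from 1.08 to 16 fragments, against a lowest value of 1.08. The test therefore cannot tell the spacer from other sequence of like GC and coverage. The strongest spacer peak lay on KI270733.1 at 141534 to 141830, 5.90 kb past the unit, with a fold enrichment of 4.75. It came from 48 unscaled ChIP fragments over a background of 7.49 on the scale of the control. Others lay on GL000220.1 at 120760 to 121065 (4.16) and 141938 to 142253 (3.10) and on chromosome 21 at 8219634 to 8219924 (3.97). Replicates 1 and 2 held 0 peaks there, against 0.0992 and 0.0394 at their densities, and the test of their shares against that of replicate 3 did not pass (Fisher's exact test, p 0.376 and 1), so a difference was not detectable at these list lengths. The spacer count was 1 at −log10 q of at least 5, 0 at a fold enrichment of at least 5, 5 at equal list lengths and 0 in single-copy peaks. Copies of the spacer are near-identical, so the peaks are not independent, and the window was chosen after these peaks were seen.

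Single-copy regions shared by a pair of lists included the promoters of NPAS4, an activity-dependent transcription factor (chromosome 11, 66421573 to 66422195, 3.91 ± 0.872), MED23, a Mediator subunit (chromosome 6, 131627885 to 131628486, 3.51 ± 0.169), and RAB3C, a vesicle GTPase (chromosome 5, 58583085 to 58583737, 3.81 ± 0.242). Introns of ALK, a receptor tyrosine kinase (chromosome 2, 29293643 to 29294431, 3.88 ± 1.42), and ERCC6L2, a DNA repair helicase (chromosome 9, 95987654 to 95988156, 3.83 ± 0.283), were shared as well (SD, n = 2 each). These genes were picked after their values were seen. Cell death genes with peaks but no shared region included CASP8 (fold enrichment 3.63 in replicate 1 and 4.12 in replicate 3, at different positions) and RIPK1 (2.13 in replicate 3).

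No biological explanation was tested, since a single group of samples was analysed.

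The multi-copy share of shared regions was the first pattern weighed. The tables argue against GC content and against the long list of replicate 3 as the whole cause: the odds ratio of multi-copy sequence in shared regions was 6.74 within GC steps of 5 points, and 7.37, 6.03 and 6.71 within the lists of replicates 1, 2 and 3, so at least 6.03. Higher coverage of multi-copy sequence in ChIP and control alike remains open and may explain it, because the background under shared multi-copy peaks was at least 2.05 times that under single-list single-copy peaks (median 2.72, 2.11 and 3.0 against 1.01, 1.03 and 1.08 fragments). Multi-copy peaks in 1 list had the same low median background as single-copy peaks (1.01, 1.03 and 1.08), so this explanation reaches only the multi-copy sequence under shared peaks, whose median fold enrichment was also higher (3.55, 3.56 and 3.64 against 3.20, 3.21 and 3.24).

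For the second pattern, the uneven chromosome densities, copy number of the A549 chromosomes is a candidate explanation: in replicate 3 the share of single-copy peaks above the lowest background correlated with density (23 chromosomes, rho 0.585, permutation p 0.00392, adjusted 0.00784; r 0.558, permutation p 0.00591, adjusted 0.0118, and 0.799 without 2 chromosomes), at 8.59% on chromosome 13, 29.3% on 2 and 30.4% on 20. Chromosomes 17 and 19 went against it, with the highest shares (34.9% and 32.0%) at replicate 3 densities of 0.654 and 0.764. Replicates 1 and 2, with as few as 1 single-copy peak on a chromosome, gave rho 0.272 and 0.274 (permutation p 0.208 and 0.205, adjusted 0.238 each; r 0.143 and 0.262). The test planned for copy number used the mean background over all peaks and predicted a positive correlation with density. It gave rho −0.504 (permutation p 0.0145, bootstrap 95% interval −0.773 to −0.0964), which goes against copy number. That mean was set by multi-copy peaks (7.36 for all and 1.03 for single-copy peaks on chromosome 18 in replicate 1), which limits the planned test. The single-copy measure was chosen after the result was seen and passed in replicate 3 alone. Neither measure settles the question. An influence of chromosome GC cannot be told apart from none, at rho 0.140 (bootstrap 95% interval −0.359 to 0.584).

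The size of the replicate 3 list was the third pattern. A deeper ChIP library is argued against by the expected fragments per shortest peak width, 0.842 times the mean of replicates 1 and 2, and a single library called again under another name by the 5.70% of replicate 1 intervals that overlap replicate 3. A GC bias of the replicate 3 library remains open and may account for the surplus over replicate 1, since that excess was 14.9 times greater at 50% GC or more than below 45% (ratios of 15.4 and 1.03). Against replicate 2 the ratio below 45% GC was still 3.05 (644 against 211 peaks), a surplus that such a bias would not cover.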
